A study of Mus musculus with 42 samples.

How the data were processed

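Mouse embryos of the strain B6D2F1 were injected at the 1-cell stage with a morpholino, an antisense oligomer that blocks the translation or the splicing of its target mRNA and need not lower the amount of that mRNA. The labels do not state which of these actions each oligomer has. Targets were Oct4 (gene symbol Pou5f1), Sall4 and Nanog, and the control oligomer matches no mouse sequence, per the labels' protocols. Embryos were cultured in human tubal fluid medium, and uninjected embryos were cultured beside them. RNA of embryos collected 20 h or 44 h after injection was isolated with a PicoPure kit, amplified from small amounts with NuGEN WT-Ovation One-Direct reagents and labelled with biotin for Affymetrix arrays, per the labels' protocols. Such amplification copies few molecules many times, so a transcript near the floor can be bright on 1 array and dark on its replicate.

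The deposited table holds 1 intensity per probe set and array for 45101 probe sets and 42 arrays. How the authors turned scanner images into the deposited intensity values, and whether arrays were normalized against each other, is not given in the sources used here. The values are on a linear scale, run down to exactly 1 (46022 values, 2.43% of the table) and show no negative number. The 18 arrays of the Nanog experiment have medians of 193 to 227 and trimmed means of 905 to 1045, and the other 24 arrays have medians of 26.1 to 33.3 and trimmed means of 188 to 235. Each injection was therefore compared with embryos of its own experiment and time. Uninjected embryos compared between experiments, and levels of 44 h set against 20 h outside the Nanog experiment, cross separately labelled experiments. A single value stands far above all others: 1 probe set reads 133546 on 1 array of Nanog morpholino embryos at 20 h and 86.7 to 98.6 on its replicates, while the next highest value of the table is 19970.39. This probe set was kept as deposited.

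Samples were grouped by time, injection and experiment from their titles, which gave 14 groups of 3 arrays. Titles number the arrays of a group as biological replicates, and p-values measure the spread between these arrays. Every array was compared with its replicates. Pearson correlations of log2 values between replicates were 0.913 to 0.947 in the Nanog experiment and 0.900 to 0.962 elsewhere, and the highest correlation of any pair of arrays was 0.964, so no array was a copy of another.

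Probe sets were named through the platform annotation. Of the probe sets, 34945 carry 1 gene symbol, 932 several, 9160 none and 64 are controls. Entrez identifiers of 34741 were found in the RefSeq gene table, which changed 0 symbols. Each gene was represented by its probe set with the highest mean, which matters for the 9010 genes with several. Values were turned into log2(intensity + 16), so fold changes understate the change of dim genes. A gene was tested if its mean in at least 1 group was above the median of the whole table, an intensity of 71.15 (6.45 on the log2 scale). This left 15478 of 18193 genes. The cut pools both scales, so a gene can pass through the Nanog arrays while it lies near the floor on the other arrays. Such genes are part of the 15478 behind the adjusted p-values and the numbers for independent lists.

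All 42 arrays entered 1 linear model with a mean per group (limma 3.58.1, statmod 1.5.0, R 4.3.3), which has 28 residual degrees of freedom. Contrasts were tested with limma's moderated statistic, two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison, and a gene passed at an adjusted p under 0.05. This gave 12 comparisons. With 3 arrays against 3, an exact permutation test of 1 gene cannot go below p = 0.1, so the test leans on a spread shared across groups and genes. The 3 uninjected groups at 20 h were compared with limma's moderated F test. Beside each value stand the mean and SD of the deposited intensity over n = 3 arrays. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

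Gene lists were written before the data were examined, and 21 had at least 5 tested members. Camera of limma tested each list with a preset correlation between genes of 0.01, and adjusted p-values cover 252 tests of 21 lists in 12 comparisons. Camera with an estimated correlation and fry of limma were alternatives. Of the 54 list calls, 3 held with an estimated correlation: the stress response list with the Oct4 morpholino at 44 h against both the control and the Sall4 morpholino, and the maternal oocyte transcripts over time in uninjected embryos. Median, mean and test had the same sign in every one of the 54. Counts of list members are given over all genes tested and adjusted over the list alone.

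Named genes followed a rule fixed before the data were examined. Pou5f1, Sall4 and Nanog were named in every comparison. In each knockdown comparison, the 10 largest rises and the 10 largest falls were named among genes that passed and whose arrays did not overlap between groups, and 5 of each in the other comparisons. Clone and accession names were passed over. Up to 4 passing members per list with the smallest adjusted p were added, as was every passing gene of the lists of other cell types. Genes chosen after their values were seen are said to be so. Of the 483 named results that passed, 269 had other probe sets, 509 in all. Among these, 239 moved the same way and 6 the opposite way at an unadjusted p under 0.05 in limma.

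Alternatives were median centring, quantile normalization, pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, the mean of all probe sets, only the arrays of the experiment, array weights, a variance trend with a robust prior, the replicate number as a block, other controls where an experiment held uninjected and control-injected embryos (the Nanog experiment at 20 h, and 44 h), and leaving out each array in turn. Scaling to a 2% trimmed mean and a filter on each array's own median were chosen after seeing the data. So were 2 comparisons of knockdown against uninjected embryos across time. The replicate numbers of 14 pairs of groups were checked for pairing by correlating deviations from group means. Values ran from -0.045 to 0.137, and only uninjected against control-injected embryos of the Nanog experiment at 20 h had every value over 0.1, so the blocked count is given there.

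The fit was tested on simulated data with 200 changed genes among the 15478, once for each comparison. Over the 12 comparisons it recovered 0 to 5.97% of genes changed by 0.5 on the log2 scale, 5.97 to 29.9% of those changed by 1 and 28.8 to 77.3% of those changed by 2, and 3.7 to 9.72% of its calls were false. Camera called 12 of 12 lists shifted by 0.5 and 1 of 240 unshifted ones. The simulated noise was independent between genes, so these numbers do not measure false list calls among correlated genes. Each gene was also given the same spread on every array, as the fit assumes. The shares recovered and the share of false calls therefore do not test the fit where spreads differ between experiments. The number of arrays limits the precision of every value. In these simulations, with 200 changed genes, changes of 0.5 or 1 on the log2 scale were mostly not detected. Some changes below 1 did pass in comparisons with more calls.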

Results

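Transcript levels were measured on 42 Affymetrix arrays of mouse embryos injected at the 1-cell stage with a morpholino against Oct4, Sall4 or Nanog. These factors belong to the pluripotency network. Other embryos received a control morpholino or were left uninjected. The design asks which transcripts depend on each factor 20 h and 44 h after injection, and sets each injection beside embryos of its own experiment. Each of the 14 groups had 3 arrays. At 20 h, the Oct4 and the Sall4 experiment each held a knockdown and an uninjected group, and the Nanog experiment also held control-injected embryos. At 44 h, Oct4 and Sall4 knockdowns shared 1 set of uninjected and control-injected embryos, and the Nanog experiment had its own. Array medians were 193 to 227 in the Nanog experiment and 26.1 to 33.3 on the other 24 arrays. The number of arrays limits the precision. Levels below are intensities as deposited, mean ± SD over n = 3 arrays, and fold changes are log2 values with their standard error (SE). Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

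The mRNA of the targeted gene passed the test at 20 h with none of the 3 morpholinos. Pou5f1, which encodes Oct4, was at 3293 ± 466 with the Oct4 morpholino and 2803 ± 203 without (log2 0.22, SE 0.186, adjusted p = 0.857). Sall4 was at 2160 ± 534 with its morpholino against 2153 ± 541 (log2 0.00, adjusted p = 1), and Nanog at 83.2 ± 53.2 against 111 ± 76.0 in control-injected embryos (log2 -0.29, adjusted p = 1). At 44 h, Pou5f1 fell with the Oct4 morpholino, from 3925 ± 456 in control-injected embryos to 2218 ± 260. Sall4 was at 3662 ± 462 with the Sall4 morpholino and 3169 ± 385 with the control (log2 0.21, adjusted p = 0.702), and Nanog at 2687 ± 1129 against 3828 ± 110 (log2 -0.61, adjusted p = 0.654). A morpholino acts on translation or splicing, so these mRNA levels do not measure the knockdown of the protein and check the labels only in part.

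**Figure D1:**
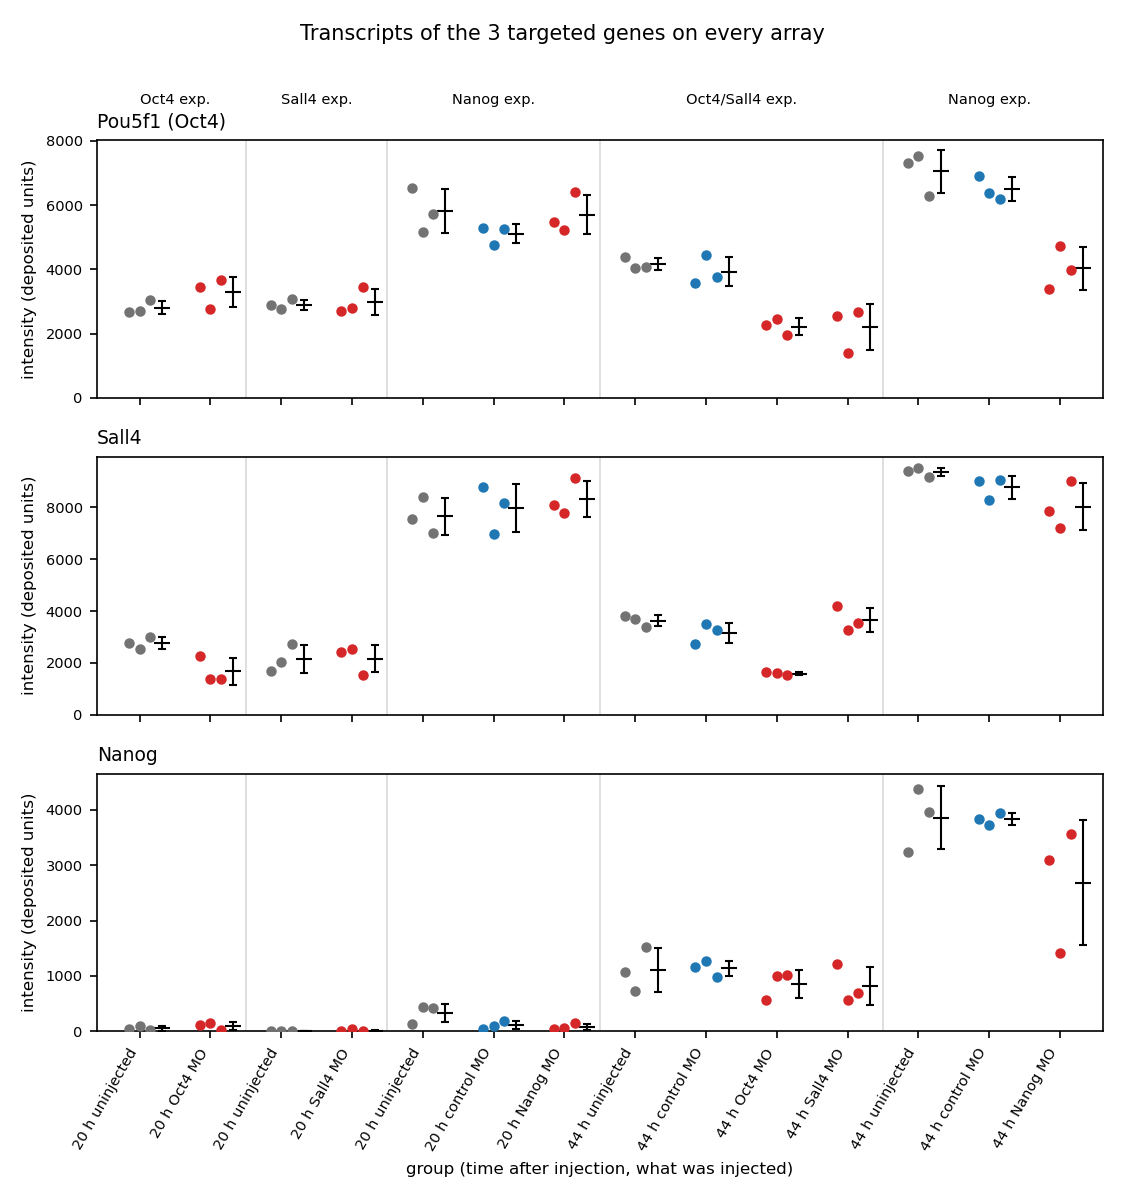
Intensities as deposited (vertical axis, linear) of Pou5f1, Sall4 and Nanog on every array, by group, with the mean and SD of n = 3 arrays beside the points; grey marks uninjected, blue control-injected and red knockdown embryos. At 44 h, Pou5f1 was lower with all 3 knockdown morpholinos, and Sall4 was lower with the Oct4 morpholino (1585 ± 64.6) than in control-injected embryos (3169 ± 385).

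Across the 3 knockdowns at 44 h, the Pou5f1 mRNA fell in each. The log2 change was -0.82 (SE 0.186, adjusted p = 0.00323) with the Oct4 morpholino. It was -0.88 (adjusted p = 0.00455) with the Sall4 morpholino, from 3925 ± 456 to 2203 ± 712. With the Nanog morpholino it was -0.70 (adjusted p = 0.0236), from 6495 ± 376 to 4034 ± 665. The Sall4 mRNA fell with the Oct4 morpholino at both times, against unlike controls. At 20 h it fell from 2765 ± 229 in uninjected embryos to 1675 ± 525 (log2 -0.76, SE 0.193, adjusted p = 0.03). At 44 h it fell from 3169 ± 385 in control-injected embryos to 1585 ± 64.6 (log2 -0.99, adjusted p = 0.000725). The fall of Pou5f1 lost its call with the arrays of the experiment alone (adjusted p = 0.0855, 0.145 and 0.122 for Oct4, Sall4 and Nanog). With the Sall4 morpholino it was also lost under quantile normalization (0.0672) and without Sall4 morpholino replicate 2 (0.0795). With the Nanog morpholino it was lost without control replicate 1 (0.0828), control replicate 2 (0.0692) or Nanog morpholino replicate 1 (0.147). At 20 h, the fall of Sall4 lost its call under quantile normalization (0.0879), the mean of all probe sets (0.0974) and the arrays of the experiment alone (0.269). It was also lost without uninjected replicate 1 (0.124), uninjected replicate 3 (0.154), Oct4 morpholino replicate 2 (0.193) or Oct4 morpholino replicate 3 (0.204). The fall at 44 h passed in all 21 other settings.

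In uninjected embryos of the Nanog experiment, maternal oocyte transcripts and those of the 2-cell stage were lower as lists at 44 h than at 20 h, and oxidative phosphorylation was higher. The maternal list held with an estimated correlation (adjusted p = 0.0142), and the others did not (0.196 and 0.068 with an estimated correlation). Of 30 maternal oocyte transcripts, 22 fell (23 adjusted over the list alone). Among them were Tcl1, an egg-enriched activator of Akt (5885 ± 837 to 232 ± 117), Bcl2l10, an apoptosis regulator of the oocyte (7921 ± 338 to 554 ± 418), and Bmp15, an oocyte growth factor (7826 ± 316 to 2592 ± 198). The 2-cell-stage transient transcripts had 9 of 14 members lower and 1 higher (10 and 2 adjusted over the list alone), such as Usp17la, a deubiquitinase (log2 -3.73, SE 0.496), and Rfpl4b (-5.17, SE 0.426). Among 78 genes of oxidative phosphorylation 34 rose and 1 fell (42 and 1 adjusted over the list alone), with Ndufa5, a subunit of complex I, at 3.54 (SE 0.439). Nanog itself rose from 330 ± 167 to 3858 ± 573 (log2 3.63, SE 0.528, adjusted p = 3.97e-06), and so did Tdgf1, a Nodal co-receptor (4.15), Esrrb, a nuclear receptor of pluripotent cells (3.19), Gata6, a factor of primitive endoderm (4.02), and Cldn4, a tight junction protein (5.35).

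In all, 3958 genes passed over this interval, 1437 higher and 2521 lower. Sall1, a relative of Sall4, rose (18.4 ± 2.23 to 4149.9 ± 551, log2 6.91) and Glis3, a zinc finger factor, fell (-6.52). The size of such changes from or to the low end depends on the pseudocount, with Sall1 at 7.74 and 5.67 and Glis3 at -7.06 and -5.55 for pseudocounts of 1 and 64. The shift of maternal transcripts had a median of -1.56 and held under both correlations of camera (adjusted p = 1.54e-09 and 0.0142). Calls that were lost with an estimated correlation were those of the 2-cell-stage list (median -1.92, adjusted p = 0.000259, and 0.196 with an estimated correlation) and oxidative phosphorylation (median 0.72, 1.54e-09 and 0.068). So were those of ribosomal proteins (19 of 47 higher, 25 over the list alone, 6.28e-08 and 0.408) and proteasome subunits (15 of 41 higher and 4 lower, 21 and 4 over the list alone, 7.31e-05 and 0.289). The remaining such calls, with the same counts over the list alone, were translation factors (14 of 53 higher and 3 lower, 0.00476 and 0.408), splicing factors (10 of 41 higher and 3 lower, 0.0398 and 0.481) and pluripotency genes (6 of 23 higher and 1 lower, 0.0179 and 0.408). The stress response list had 9 of 24 members lower and 0 higher, also over the list alone, but did not pass (adjusted p = 0.174), with Egr1, an immediate early factor, at -3.08 and Gadd45a, a growth arrest gene, at -3.48. Greb1, of the granulosa cell list, also fell (215 ± 157 to 36.96 ± 6.96, adjusted p = 0.0161). That call was lost without 20 h uninjected replicate 1 (0.134) or 2 (0.101), without 44 h uninjected replicate 1 (0.057), and with the arrays of the experiment alone (0.0766). Dab2 fell, an endocytic adaptor, by 1.48 on the log2 scale, but another of its probe sets stood at 1.48. Of the 83 named genes that passed, 74 passed without each array in turn and 79 with the arrays of the experiment alone.

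Between control-injected and uninjected embryos, 15 genes passed at 44 h in the Oct4 and Sall4 experiment and 54 in the Nanog experiment, and 2 genes fell in both. Rpl39l, a ribosomal protein copy, fell from 2367 ± 186 in uninjected to 508 ± 38.1 in control-injected embryos of the Oct4 and Sall4 experiment (log2 -2.18, SE 0.357, adjusted p = 0.0047). In the Nanog experiment it fell from 5953 ± 1208 to 1470.2 ± 54.8 (-1.99, adjusted p = 0.00679). Gtf2f2, a subunit of the general transcription factor TFIIF, fell by 1.22 (adjusted p = 0.0111) and by 1.49 (adjusted p = 0.001) on the log2 scale. Independent lists would share 0.00905 genes, a number that leaves out the spread of each gene, estimated once for both comparisons. In the former experiment, the call of Gtf2f2 was lost without uninjected replicate 2 (0.0787), control replicate 1 (0.12) or control replicate 3 (0.0609), and with the arrays of the experiment alone (0.356). In the latter, that of Rpl39l was lost without uninjected replicate 2 (0.0557) and with the arrays of the experiment alone (0.126).

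In the Oct4 and Sall4 experiment at 44 h, 15 genes passed, 10 higher and 5 lower, including Prkaca, a catalytic subunit of protein kinase A (log2 2.51, SE 0.366), and Snrnp48, of the minor spliceosome (1.33, SE 0.186). Ribosomal proteins were lower (median -0.08, 1 of 47 members lower, also over the list alone, adjusted p = 0.0389, and 0.73 with an estimated correlation). Markers of blood, stroma and fibroblasts were lower as well (median -0.25, 0 of 11 members past the test and 0 adjusted over the list alone, adjusted p = 0.0364, and 0.17 with an estimated correlation). The count was 3 with the mean of all probe sets, 27 with array weights, 1 with the arrays of the experiment alone, 6 without uninjected replicate 3 or control replicate 1 and 4 without control replicate 3. Quantile normalization split 19 calls into 8 higher and 11 lower.

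In the Nanog experiment at 44 h, 54 genes passed, 26 higher and 28 lower, and 0 lists. Besides Gtf2f2, the named genes that passed without each array in turn were Eri3, an exoribonuclease (log2 -1.83, SE 0.308), and Taf6, of the TFIID complex (1.55, SE 0.294). Median centring, which moved the median of all genes by 0.12, gave 32 higher and 7 lower, quantile normalization 8 and 4, and scaling to a trimmed mean 10 and 3. Leaving out uninjected replicates 1 or 2 or control replicates 2 or 3 gave 114, 15, 87 and 22 genes. Pseudocounts of 1 and 64 gave 10 and 314 genes, array weights 192, a filter at the 75th percentile 25, and a filter on the arrays' own medians 29. The arrays of the experiment alone gave 0 in limma, with 1566 at an unadjusted p under 0.05.

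At 20 h in the Nanog experiment, 14 genes passed, 9 higher with the control morpholino and 5 lower. Elp3, an acetyltransferase of the Elongator complex, was higher (log2 2.78, SE 0.525, adjusted p = 0.023). Its call was lost without uninjected replicate 3 (0.0557), control replicate 1 (0.0793) or control replicate 3 (0.127). Genes of oxidative phosphorylation were higher by a median of 0.10 with 0 of 78 members past the test and 0 adjusted over the list alone (adjusted p = 0.0133, and 0.444 with an estimated correlation). Nanog was at 111 ± 76.0 against 330 ± 167 (log2 -1.48, adjusted p = 0.492). Each of the 10 named genes that passed lost its call without at least 1 of the 6 arrays. The replicate number as a block left 8 genes, and the count was 28 without uninjected replicate 1, 53 without uninjected replicate 2 and 7 without control replicate 1. Limma called 2 genes under quantile normalization (1 higher, 1 lower), 9 with array weights or a filter at the 75th percentile, and 52 with a pseudocount of 64. It called 0 with a pseudocount of 1, a trimmed mean or the arrays of the experiment alone, with 546, 552 and 688 genes at an unadjusted p under 0.05.

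**Figure D2:**
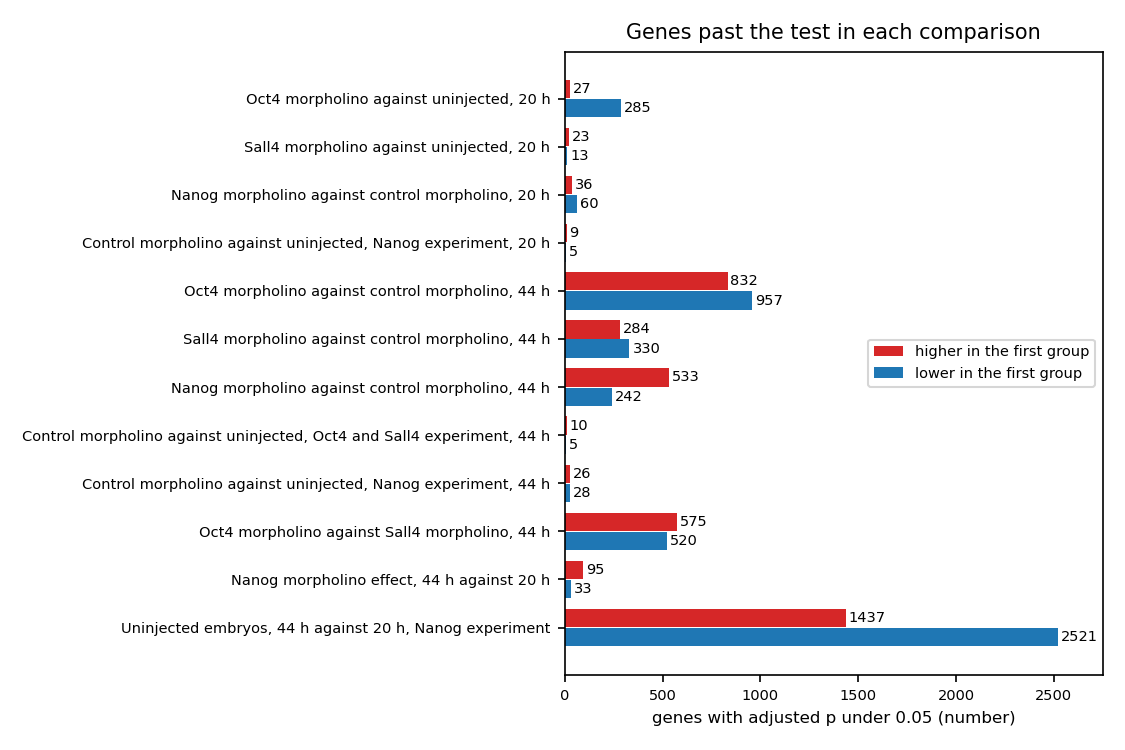
Number of genes with an adjusted p under 0.05 (horizontal axis, linear) in each of 12 comparisons, split into genes higher (red) and lower (blue) in the first group named. The Oct4 morpholino at 44 h had 832 genes higher and 957 lower, and the control morpholino against uninjected embryos 5 to 28 in a direction.

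With the Oct4 morpholino at 44 h, the lists of the stress response and of the 2-cell stage were higher than in control-injected embryos, and translation factors, proteasome, oxidative phosphorylation and chromatin regulators were lower. Of these calls that of the stress list held with an estimated correlation (adjusted p = 0.00948), and the others did not (0.068, 0.289, 0.372, 0.408 and 0.241 in this order). Of 24 stress response genes 8 rose and 0 fell (11 and 1 adjusted over the list alone). Among them were Hspa1a, an inducible chaperone (185 ± 124 to 2191 ± 565, log2 3.60, SE 0.402), Egr1 (49.8 ± 60.4 to 725 ± 154) and Gadd45g (33.6 ± 12.8 to 408 ± 285). Of 14 transcripts of the 2-cell stage 8 rose (9 over the list alone), such as Usp17la (52.9 ± 34.5 to 1198 ± 388), Arg2, an arginase (96.6 ± 8.90 to 796 ± 164), and Spz1, a transcription factor (417 ± 311 to 1890.5 ± 320). The largest fall was that of Psmb2, a proteasome subunit (1812 ± 496 to 47.2 ± 37.5, log2 -4.97, SE 0.291, adjusted p = 4.27e-13). The largest rises were those of Rasl11b, a small GTPase (4.44, SE 0.677), and Ier5, an immediate early gene (4.22, SE 0.484).

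Among 53 translation factors 10 fell and 1 rose (14 and 1 adjusted over the list alone). Eif2s3x, a subunit of eIF2, fell from 2998 ± 274 to 428 ± 166, Eif3e, of eIF3, from 4339 ± 289 to 645 ± 129, and Eif4e, the cap-binding protein, from 4512 ± 266 to 1503 ± 400. Proteasome subunits had 5 of 41 lower and 1 higher, the same numbers adjusted over the list alone. Oxidative phosphorylation had 8 of 78 lower and 1 higher (8 and 1 over the list alone), with Ndufs4, of complex I, at -3.60. Splicing factors had 7 of 41 lower (10 over the list alone), with Snrpf, a core spliceosomal protein, at -1.17. Chromatin regulators had 6 of 32 lower and 2 higher (8 and 2 over the list alone): Hat1, a histone acetyltransferase (-2.03), Carm1, an arginine methyltransferase of the early embryo (-2.34), and Smarca4, the ATPase of BAF complexes (-1.61), fell. Of 31 cell cycle genes 4 fell and 1 rose, in both ways of adjusting, with Cdk1, the mitotic kinase, at -1.22 and Orc1, of the origin recognition complex, at 1.51, and the list did not pass (adjusted p = 0.199).

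Among pluripotency genes 5 of 23 fell, in both ways of adjusting, including Pou5f1, Sall4 and Fbxo15 (-0.59), and 4 of 30 maternal transcripts rose, likewise in both ways, with Nlrp4f at 1.72. The lineage lists did not pass. Of 23 trophectoderm genes 3 rose and 2 fell (3 and 3 over the list alone, adjusted p = 0.97). Atp1b1, a sodium pump subunit (367 ± 173 to 1948 ± 504), and Slc2a1, a glucose transporter (2.76), rose, and Aqp3, a water channel (1887 ± 255 to 229 ± 41.4), and Cldn4 (-3.07) fell. Of 15 primitive endoderm genes 1 fell, Dab2 (-2.21, SE 0.374). Of 17 Hippo pathway genes 3 fell (3 over the list alone, adjusted p = 0.0731), among them Amotl2, an angiomotin that binds Yap (-1.96), and Mob1a, a cofactor of the Lats kinases (-1.91). Of 15 genes of glycolysis 4 rose and 1 fell (adjusted p = 0.301), with Pgk1 at 1.49. Of 17 p53 targets 4 rose (6 higher and 1 lower over the list alone, adjusted p = 0.0575), with Trp53inp1 at 0.82. Gtf2f2 (1.93) and Rpl39l (1.69) also rose, but both had fallen in control-injected against uninjected embryos. Against uninjected embryos they stood at 0.71 (adjusted p = 0.0251) and -0.50.

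In this comparison 1789 genes passed, 832 higher and 957 lower. The stress list had a median of 0.96 and held with an estimated correlation (adjusted p = 1.75e-06, and 0.00948 with an estimated correlation). The other 9 list calls did not: transcripts of the 2-cell stage (median 1.25, adjusted p = 1.35e-06, and 0.068 with an estimated correlation), translation factors (-0.19, 4.41e-05 and 0.289), and proteasome (-0.34, 0.000318 and 0.372). Next were oxidative phosphorylation (-0.32, 0.0013 and 0.408), splicing (-0.14, 0.00258 and 0.408) and chromatin (-0.41, 0.00295 and 0.241). The others were maternal (0.34, 0.0265 and 0.408), pluripotency (-0.44, 0.0266 and 0.408) and ribosomal proteins (2 of 47 higher and 3 lower, in both ways of adjusting, -0.18, 0.0336 and 0.726). The pluripotency call was also lost under quantile normalization (adjusted p = 0.24), a pseudocount of 1 (0.0574), a filter at the 75th percentile (0.0783), the mean of all probe sets (0.0551) and a trimmed mean (0.0511). Cumulus and granulosa markers had 0 of 11 members past the test (median -0.04). A difference between groups does not show whether such cells were present. Over all arrays, the brightest members had median intensities of 1156 (Amhr2), 249 (Cyp11a1) and 156 (Star). In the list of blood, stroma and fibroblasts they had 4612 (Hba-a2), 229 (Pecam1) and 74.4 (Lyz2). The ratio of 3' to 5' probe sets of Gapdh was 2.45 ± 1.13 on the log2 scale against 1.85 ± 0.0392 in control-injected embryos. That of Actb was -0.423 ± 0.261 against -0.397 ± 0.278. The count was 1043 with the arrays of the experiment alone, 2770 against control-injected and uninjected embryos averaged, and 1161 without control replicate 2. In all, 68 of the 83 named genes that passed did so without each array in turn.

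With the Sall4 morpholino at 44 h, maternal and 2-cell-stage transcripts were higher as lists than in control-injected embryos (adjusted p = 4.42e-05 and 6.93e-06, and 0.121 and 0.0922 with an estimated correlation). Among single genes, Dab2 fell from 554 ± 144 to 69.9 ± 47.6 (log2 -2.83, SE 0.374, adjusted p = 3.21e-05), Amotl2 from 377 ± 81.4 to 53.9 ± 43.9 (-2.65, SE 0.423), and Pard6b, a cell polarity protein, from 325 ± 33.5 to 88.7 ± 14.6 (-1.71). Ccn2, a secreted target of Yap, fell from 164 ± 44.7 to 4.75 ± 0.249 (-3.08, SE 0.416), and Sdha, of respiratory complex II, from 1013 ± 126 to 169 ± 133 (-2.77). Of 30 maternal transcripts 6 rose (9 adjusted over the list alone), with Oosp1, an oocyte-secreted protein (269 ± 118 to 1079.9 ± 460), Omt2b (0.98) and Omt2a (1.03). The largest rise that passed without each array in turn was Rfx7, a winged helix factor (3.10), and Ifnar1, an interferon receptor chain, rose by 2.60 (adjusted p = 2.71e-05).

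The trophectoderm list had 2 of 23 members lower (1 higher and 2 lower over the list alone) and did not pass (adjusted p = 0.332). Cdx2, the factor that specifies trophectoderm, stood at 75.3 ± 114 against 357 ± 148 (log2 -2.75, adjusted p = 0.0411). Its call was lost without control replicates 1 (0.0791), 2 (0.0854) or 3 (0.165) and without Sall4 morpholino replicates 1 (0.165) or 2 (0.25). It was also lost with a pseudocount of 64 (0.0537), the mean of all probe sets (0.111) and the arrays of the experiment alone (0.238). The lists of primitive endoderm (1 of 15 lower, adjusted p = 0.145) and pluripotency genes (2 of 23 lower, 3 over the list alone, adjusted p = 0.0619) did not pass either. Of 78 genes of oxidative phosphorylation 7 fell (11 over the list alone), and of 31 cell cycle genes 3 fell (4 over the list alone), with Rrm2, of ribonucleotide reductase, at -0.75. Of 53 translation factors 2 fell (1 higher and 3 lower over the list alone), with Eef1b2, an elongation factor, at -1.13. The stress response list did not pass (1 of 24 higher, 2 over the list alone, median 0.18, adjusted p = 0.203). Gtf2f2 (1.84) rose here too, as did Rpl39l (1.51; adjusted p = 0.0521 without Sall4 morpholino replicate 2). Both had fallen in control-injected embryos, and against uninjected embryos they stood at 0.62 and -0.68.

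A total of 614 genes passed, 284 higher and 330 lower. No list call held with an estimated correlation: transcripts of the 2-cell stage (3 of 14 higher, 8 higher and 1 lower over the list alone, median 1.21, adjusted p = 6.93e-06, and 0.0922 with an estimated correlation), and oxidative phosphorylation (median -0.34, 8.06e-06 and 0.225). The same held for ribosomal proteins (2 of 47 lower and 1 higher, 6 and 1 over the list alone, -0.28, 2.04e-05 and 0.441) and maternal transcripts (0.42, 4.42e-05 and 0.121). It also held for proteasome (2 of 41 lower and 1 higher, 3 and 1 over the list alone, -0.27, 0.00576 and 0.408), cell cycle (-0.18, 0.00709 and 0.408), translation factors (-0.20, 0.00709 and 0.421) and splicing (1 of 41 lower, -0.17, 0.0141 and 0.408). The count was 117 with the arrays of the experiment alone, 1076 against uninjected embryos, and 1323 against both controls averaged. It was 350 without control replicate 2, 359 without control replicate 3 and 247 without Sall4 morpholino replicate 2. Scaling to a trimmed mean split it into 498 higher and 359 lower. Of the 60 named genes that passed, 25 did so without each array in turn.

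With the Nanog morpholino at 44 h, the lists of maternal transcripts and of the stress response were higher than in control-injected embryos (adjusted p = 9.97e-05 and 0.000959, and 0.152 and 0.068 with an estimated correlation). Among single genes, Nptx1, a neuronal pentraxin, rose from 279 ± 442 to 3664 ± 818 (log2 5.05, SE 0.987), and Tubb3, the neuronal tubulin, from 99.2 ± 121 to 2656 ± 1517 (4.84). Ier5 rose from 157 ± 67.9 to 3804 ± 1395 (4.46). Id2 stood at 4.78, a call that was lost with a pseudocount of 1 (0.10, adjusted p = 0.993), where another of its probe sets has the highest mean. Of 24 stress response genes 7 rose (8 adjusted over the list alone), with Gadd45a at 3.17, Fos, an immediate early factor, at 3.35 and Hspa1a at 1.95. Oosp2 (4.20) and Gdf9, an oocyte growth factor (1746 ± 166 to 3707 ± 106), were among 4 of 30 maternal transcripts that rose (7 over the list alone), and Rfpl4b (130.4 ± 29.03 to 2109 ± 1324) among 4 of 14 of the 2-cell stage (5 over the list alone). The largest falls were those of Niban1 (-4.55), Ddah1, a hydrolase of methylated arginine (-4.25), and P2ry14, a receptor of UDP-glucose (-4.23).

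Among other groups, Pfkp, a phosphofructokinase, rose by 2.25 and Pgk1 by 1.68 in a glycolysis list with 3 of 15 members higher and 1 lower (4 and 1 over the list alone) that did not pass (adjusted p = 0.19). Ocln, the tight junction protein occludin, fell from 1962 ± 105 to 404 ± 182 (-2.33, SE 0.425), in an adhesion list with 1 of 21 lower (adjusted p = 0.19). Of the trophectoderm genes 2 of 23 rose and 1 fell (adjusted p = 0.672), and the interferon response list did not pass either (1 of 12 higher, adjusted p = 0.202). Gtf2f2 (1.58) and Rpl39l (1.71) rose against control-injected embryos, where both had fallen, while against uninjected embryos they stood at 0.09 and -0.28. Amotl2 fell (-1.67, adjusted p = 0.0163), a call lost without control replicate 2 (0.0877), Nanog morpholino replicate 1 (0.0521) or 2 (0.148), with a pseudocount of 1 (0.0614) and with the arrays of the experiment alone (0.171). Dab2 fell as well (-1.35, adjusted p = 0.0299). Its call was lost without control replicates 1 (0.0628), 2 (0.0807) or 3 (0.0846) and without Nanog morpholino replicates 1 (0.196) or 2 (0.0865). It was also lost with a pseudocount of 1 (0.071), against uninjected embryos (0.186) and with the arrays of the experiment alone (0.179). Here 775 genes passed, 533 higher and 242 lower. The 5 list calls were lost with an estimated correlation: maternal transcripts (median 0.60, adjusted p = 9.97e-05, and 0.152 with an estimated correlation), and stress response (0.50, 0.000959 and 0.068). The others were pluripotency (1 of 23 lower, -0.30, 0.00826 and 0.408), 2-cell stage (0.64, 0.0203 and 0.408) and ribosomal proteins (1 of 47 higher and 1 lower, -0.10, 0.0266 and 0.72). The count was 442 and 1266 with pseudocounts of 1 and 64, and 91 with the arrays of the experiment alone. It was 1296 against uninjected embryos, 1458 against both controls averaged, 400 without control replicate 2 and 404 without Nanog morpholino replicate 1. Of the 55 named genes that passed, 25 did so without each array in turn.

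**Figure D3:**
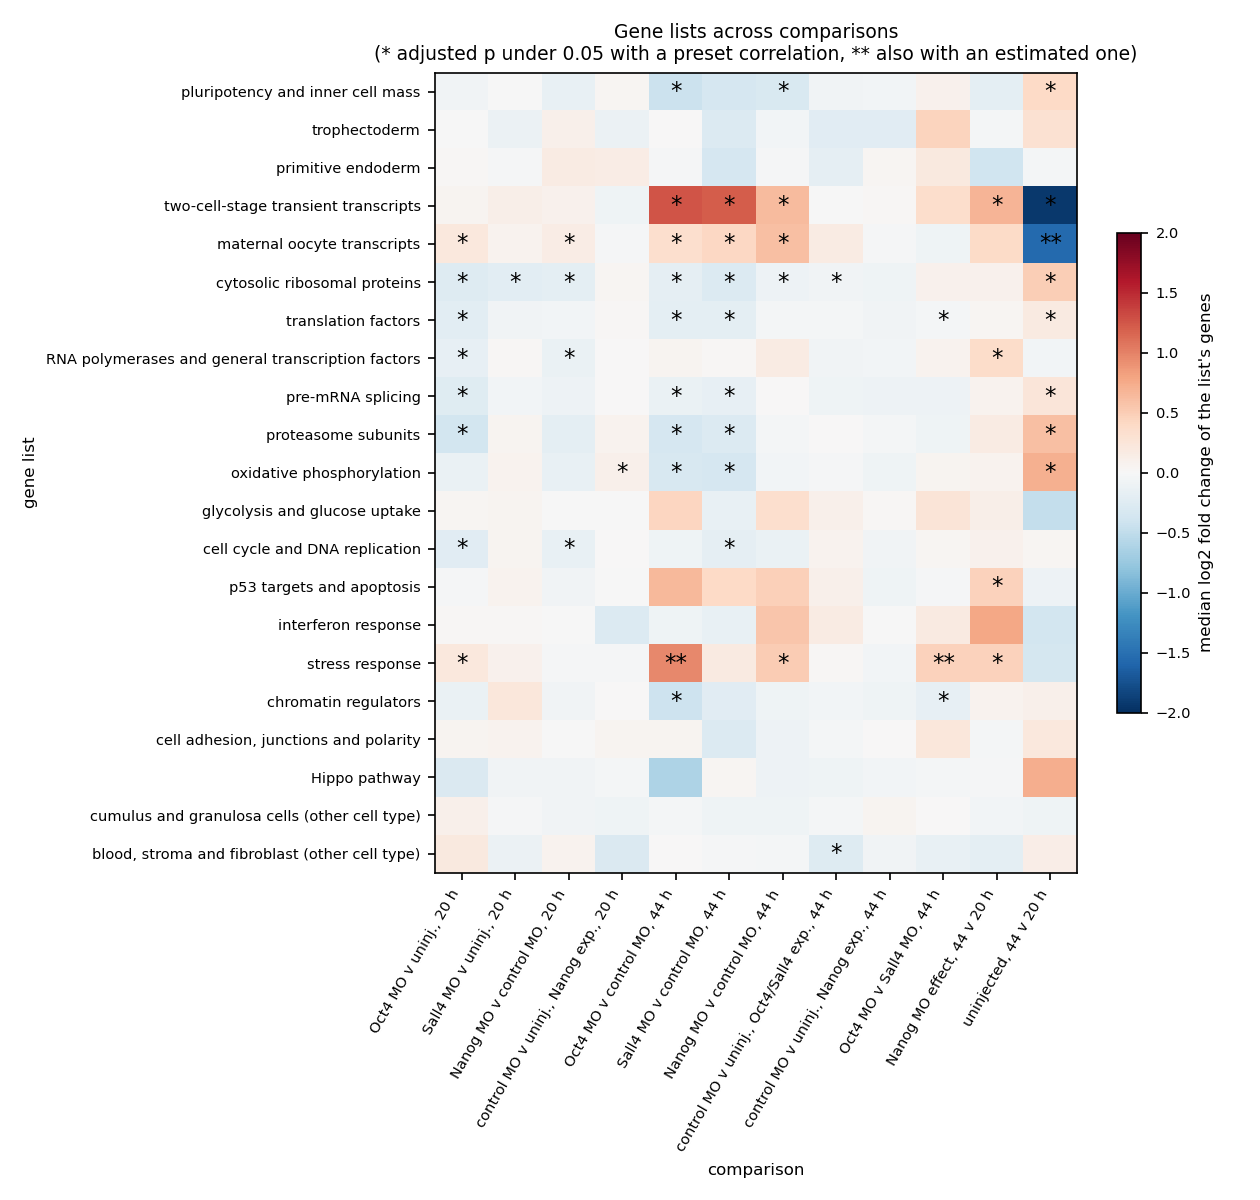
Median log2 fold change (colour) of each of 21 gene lists in 12 comparisons; 1 asterisk marks an adjusted p under 0.05 in camera with the preset correlation and 2 asterisks one that also passed with an estimated correlation. The 2-cell-stage list has medians of 1.25, 1.21 and 0.64 with the Oct4, Sall4 and Nanog morpholinos at 44 h and -1.92 between 20 h and 44 h in uninjected embryos.

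At 20 h, translation factors and proteasome subunits were lower as lists in Oct4 morpholino than in uninjected embryos (adjusted p = 0.000199 and 5.4e-08, and 0.372 and 0.1 with an estimated correlation). This experiment has no control-injected group, so an effect of injection cannot be separated from that of the knockdown. Eif3e fell from 1587 ± 136 to 365 ± 72.7 (log2 -2.09, SE 0.174, adjusted p = 5.85e-09), Eif3c, another subunit of eIF3, from 4081 ± 571 to 1735 ± 578 (-1.26), Psmb5, a catalytic proteasome subunit, from 121 ± 30.4 to 19.2 ± 17.0 (-2.05), and Mcm5, of the replicative helicase, from 2045 ± 220 to 692 ± 136 (-1.55). The chromatin genes Hat1 (-1.29) and Hdac1, a histone deacetylase (-0.68), also fell. The largest falls were those of Kank4, a cytoskeletal regulator (469 ± 102 to 29.5 ± 20.2, log2 -3.49, SE 0.394), Tmppe (-3.30) and Acyp1, an acylphosphatase (-3.28). Sfi1, a centrosomal protein (1197 ± 318 to 5800.2 ± 1278), Rps6, a ribosomal protein (108 ± 26.3 to 636 ± 133), and Gadd45g (18.3 ± 2.33 to 97.5 ± 27.4) rose.

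By list, 7 of 41 proteasome subunits fell (1 higher and 17 lower adjusted over the list alone), as did 7 of 53 translation factors (1 and 13 over the list alone). So did 4 of 41 splicing factors with 1 higher (6 and 1 over the list alone) and 2 of 55 RNA polymerase subunits and general transcription factors (1 and 7 over the list alone). In all, 312 genes passed, 27 higher and 285 lower. Each of the 8 list calls was lost with an estimated correlation: proteasome (median -0.37, adjusted p = 5.4e-08, and 0.1 with an estimated correlation), ribosomal proteins (2 of 47 lower and 1 higher, 4 and 1 over the list alone, -0.26, 7.31e-05 and 0.481) and translation factors (-0.21, 0.000199 and 0.372). Next came splicing (-0.25, 0.00225 and 0.408) and stress response (1 of 24 higher, 3 over the list alone, 0.22, 0.0038 and 0.104). The others were maternal transcripts (1 of 30 higher, 0.21, 0.00498 and 0.372), cell cycle (1 of 31 lower, 6 over the list alone, -0.23, 0.00684 and 0.408) and RNA polymerases (-0.16, 0.0123 and 0.408). The count was 195 under quantile normalization, 194 with the mean of all probe sets, 942 with array weights, and 13 with the arrays of the experiment alone. It was 97 and 125 without uninjected replicates 1 and 3, and 528, 133 and 174 without Oct4 morpholino replicates 1, 2 and 3. Of the 45 named genes that passed, 15 did so without each array in turn.

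With the Sall4 morpholino at 20 h, 36 genes passed against uninjected embryos, 23 higher and 13 lower, again without a control-injected group in the experiment. Trh, the thyrotropin-releasing hormone, fell from 667 ± 360 to 47.3 ± 15.3 (log2 -3.30, SE 0.552), and Erdr1 from 1548 ± 1492 to 275 ± 89.2 (-2.01). Zfp628, a zinc finger protein, rose from 33.8 ± 5.88 to 324 ± 145 (2.70, SE 0.412). Cyp11a1, the first enzyme of steroid synthesis and a marker of granulosa cells, rose from 25.4 ± 9.65 to 343 ± 358 (2.61, SE 0.433, adjusted p = 0.00707), while the list of cumulus and granulosa cells had 1 of 11 members past the test (1 over the list alone, median -0.03, adjusted p = 0.337). Ribosomal proteins were lower (1 of 47 members, 6 adjusted over the list alone, median -0.21, adjusted p = 1.03e-07, and 0.408 with an estimated correlation).

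Of the 22 named genes that passed, 4 did so without each array in turn. Median centring gave 55 genes (25 higher and 30 lower), quantile normalization 21 and 27, and a trimmed mean 50 and 50. Pseudocounts of 1 and 64 gave 56 and 11, the mean of all probe sets 16, array weights 15, and a variance trend 67. The arrays of the experiment alone gave 0 in limma, with 954 at an unadjusted p under 0.05. The count was 184 without uninjected replicate 1, 81 without uninjected replicate 2 and 56 without Sall4 morpholino replicate 2. Log2 ratios of 3' to 5' probe sets spread widely between the uninjected arrays, at 2.27 ± 1.59 for Gapdh and -0.566 ± 1.40 for Actb. In Sall4 morpholino embryos they were 2.19 ± 0.987 and -0.455 ± 0.361.

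With the Nanog morpholino at 20 h, 96 genes passed against control-injected embryos, 36 higher and 60 lower. Ewsr1, an RNA-binding protein, fell from 1759.8 ± 321 to 177 ± 76.8 (log2 -3.27, SE 0.335, adjusted p = 9.48e-07), Rhov from 1015 ± 399 to 43.5 ± 58.8 (-4.48), and Rrm1, of ribonucleotide reductase, from 3685 ± 930 to 1108 ± 427 (-1.76). Cacna1d, a calcium channel, rose from 99.8 ± 55.1 to 1074 ± 238 (3.34, SE 0.515), and Runx3, a runt-domain factor, from 8.85 ± 3.50 to 414 ± 459 (3.29). Lists moved by medians of 0.19 or less: ribosomal proteins (1 of 47 higher and 1 lower, -0.19, adjusted p = 0.000157, and 0.513 with an estimated correlation), and cell cycle (1 of 31 lower, 2 over the list alone, -0.15, 0.00698 and 0.408). Others were RNA polymerases (0 of 55, 1 lower over the list alone, -0.14, 0.0109 and 0.408) and maternal transcripts (0 of 30, 0.16, 0.0303 and 0.408). The count was 35 and 170 with pseudocounts of 1 and 64, 43 with a trimmed mean, and 0 in limma with the arrays of the experiment alone (1096 at an unadjusted p under 0.05). It was 60 and 42 without control replicates 1 and 2 and 48 without Nanog morpholino replicate 1. The mean of all probe sets ended the calls of Ewsr1 (0.0783) and Rrm1 (0.572), and uninjected embryos as control that of Rhov (0.2). In all, 7 of the 25 named genes that passed did so without each array in turn.

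Set directly against each other at 44 h, Oct4 morpholino embryos had more stress transcripts and less of several translation factors than Sall4 morpholino embryos. Hspa1a stood at 2191 ± 565 against 178 ± 55.5 (log2 3.51, SE 0.402), Gadd45g at 408 ± 285 against 33.7 ± 6.91, and 7 of 24 stress genes were higher (9 adjusted over the list alone, median 0.46, adjusted p = 2.93e-05, and 0.0142 with an estimated correlation). Eif2s3x (-2.45), Eif3e (-2.18), Eif4e (-1.70) and Psmb2 (-4.71) were lower with the Oct4 morpholino, as were Hells, a chromatin remodeller (1222 ± 113 to 86.2 ± 63.4), and Sall4 itself (3662 ± 462 to 1585 ± 64.6, -1.19, adjusted p = 0.000144). Orc1 stood at 789 ± 38.3 against 96.6 ± 80.1 (3.06), Atp1b1 was higher (2.61) and Aqp3 lower (-2.58), and the maternal Oosp1 was lower (-2.27). Pou5f1 (0.06, SE 0.186, adjusted p = 0.929) did not pass. In all 1095 genes passed, 575 higher and 520 lower. Translation factors (2 of 53 higher and 5 lower, median -0.05, adjusted p = 0.0456, and 0.556 with an estimated correlation) and chromatin regulators (5 of 32 lower, 1 higher and 5 lower over the list alone, -0.16, 0.0378 and 0.408) passed with the preset correlation alone. The count was 700 with array weights and 481 with the arrays of the experiment alone.

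The Nanog morpholino effect differed between 44 h and 20 h for 128 genes, 95 of them higher at 44 h and 33 lower, tested as the difference of both effects. Rfpl4b (log2 3.58, SE 0.602, adjusted p = 0.00416) and Pfkp (2.36, SE 0.452) differed upwards, and Pou5f1 stood at -0.85 (SE 0.263, adjusted p = 0.142). Lists with a positive difference were RNA polymerases (median 0.37, 0 of 55 members past the test, adjusted p = 0.00121, and 0.408 with an estimated correlation), stress response (1 of 24, 3 over the list alone, 0.46, 0.00596 and 0.121), the 2-cell stage (1 of 14, 3 over the list alone, 0.68, 0.0242 and 0.408) and p53 targets (1 of 17, 3 over the list alone, 0.46, 0.0293 and 0.408). Quantile normalization gave 62 and 43 genes, a trimmed mean 21 and 14, pseudocounts of 1 and 64 a total of 39 and 303, and the arrays of the experiment alone 12. Without control replicates 1 or 3 or Nanog morpholino replicate 1 of 20 h, the count was 71, 79 and 82, and without Nanog morpholino replicate 1 of 44 h it was 75.

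Calls of the 3 knockdowns at 44 h overlapped. Oct4 and Sall4 morpholinos shared 154 genes higher and 137 lower, where independent lists would share 15.3 and 20.4, and 7 went opposite ways (35.3 for independent lists). They share control arrays, and with uninjected embryos as the control of Sall4 the overlap was 186 higher and 171 lower (29.7 and 32.4 for independent lists). Oct4 and Nanog, which share no array, had 145 genes higher and 53 lower in common (28.7 and 14.96 for independent lists), and Sall4 and Nanog 54 and 14 (9.78 and 5.16). In all 3, 39 genes rose (0.526 for independent lists) and 9 fell (0.319): Amotl2, Dab2, Dync2h1, Ect2, Ift43, Mpzl2, Pou5f1, Sdha and Ywhab. The 39 include Gtf2f2 and Rpl39l, which had fallen in control-injected embryos, and independent lists leave out the control arrays that Oct4 and Sall4 share. Such lists also leave out the spread of each gene, which 1 fit estimates for all comparisons. Genes of small spread pass more often in each, so independent lists are too low a baseline, also without shared arrays. This would raise opposite calls too, which were 10 for Oct4 and Nanog (45.96 for independent lists) and 5 for Sall4 and Nanog (15.8). With uninjected embryos as control of Sall4, a setting chosen after the data were seen, 48 genes rose in all 3 (1.02 for independent lists; 30 of the 39) and 19 fell (0.507; each of the 9). Of the 9, Dync2h1, Ect2, Ift43, Mpzl2 and Ywhab lie outside the rule for named genes and were chosen after their values were seen. Across genes, which are not independent replicates, fold changes of Oct4 and Sall4 correlated with r = 0.53 at 44 h (Spearman 0.50), where unchanged groups against the same controls gave 0.50 in simulations. The covariance was 0.292 against a simulated 0.123, a difference of 0.170. Without shared arrays r was 0.40, and it was 0.34 for Oct4 and Nanog, 0.28 for Sall4 and Nanog, and 0.09, 0.16 and 0.03 for the same pairs at 20 h. With the effect of control injection in the Nanog experiment at 20 h, r was -0.0558 for Oct4 and 0.0242 for Sall4.

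**Figure D4:**
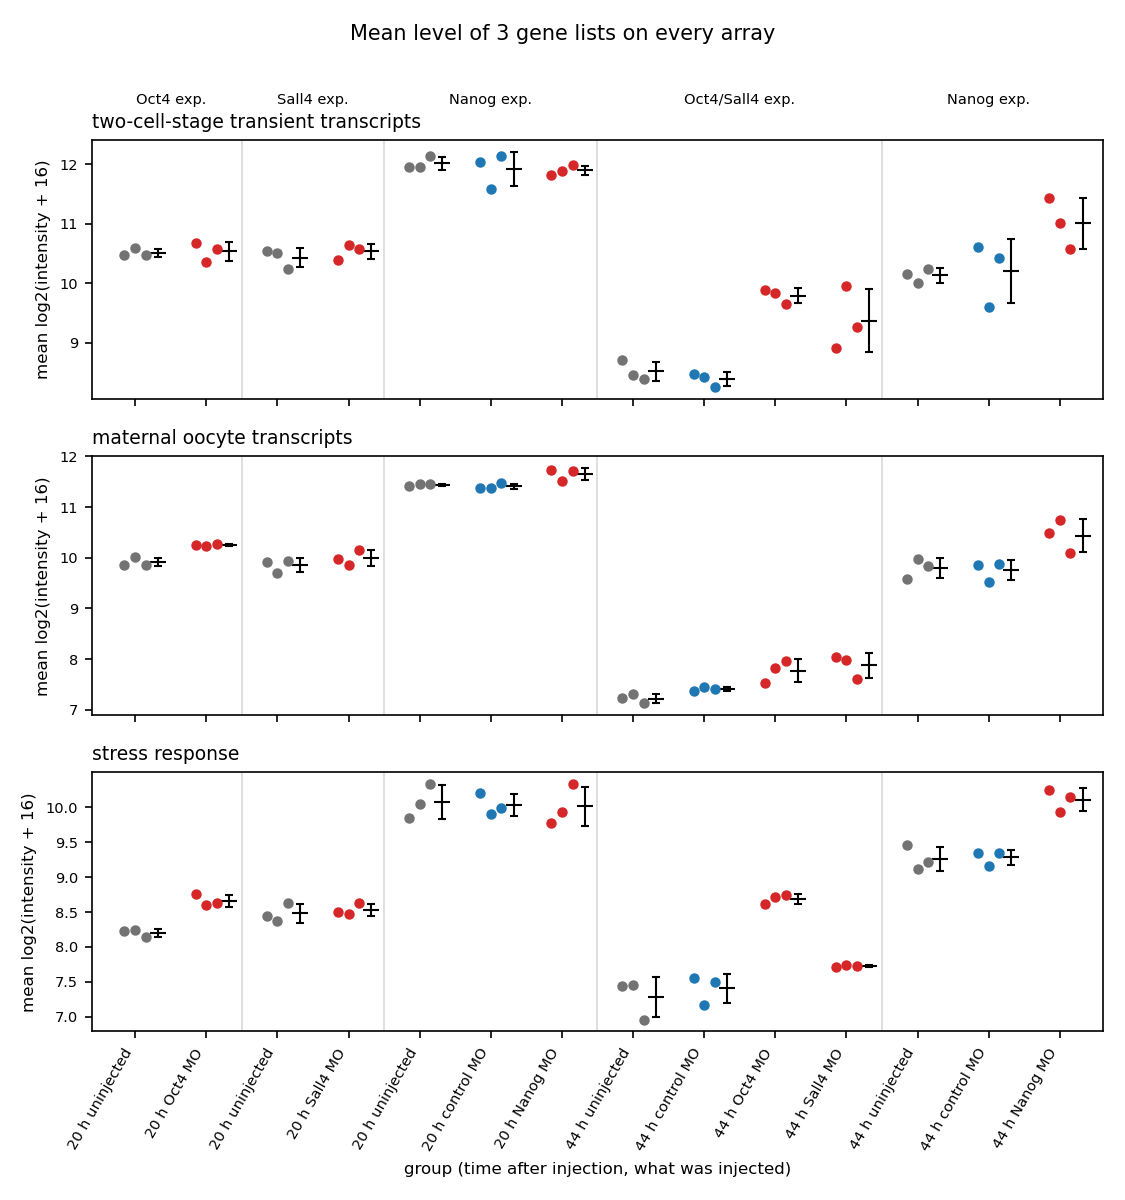
Mean log2(intensity + 16) of the tested members of 3 lists on every array, by group, with the mean and SD of n = 3 arrays; grey marks uninjected, blue control-injected and red knockdown embryos, and the Nanog experiment lies on a higher scale. With the Oct4 and the Nanog morpholino at 44 h, the stress response list was higher than in control-injected embryos, by medians of 0.96 and 0.50 (adjusted p = 0.00948 and 0.068 with an estimated correlation, so that the Nanog call was lost).

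Between experiments, uninjected embryos at 20 h differed in 13790 genes in limma's F test as deposited, a count that holds the difference in scale of the Nanog experiment. It was 4994 after median centring, 3943 under quantile normalization and 5330 with a trimmed mean. Over all comparisons, 7 lists passed in none: trophectoderm, primitive endoderm, glycolysis, interferon response, adhesion and polarity, the Hippo pathway, and cumulus and granulosa cells. Besides the calls lost with an estimated correlation or with fry, 38 of the 54 list calls held in every setting run for lists. The other 16 were lost in at least 1. List tests were not run with arrays left out, with the arrays of the experiment alone or with other controls.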

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

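The splits of the Nanog comparison across time were planned, while the other comparisons across time with their splits, the probe sets without a single gene name and all tests of the 3 patterns below were chosen only after the result was seen. Groups of 3 arrays were not searched for single arrays far from the others.

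Effects that differed between 20 h and 44 h in a test of the difference itself drew attention first. The Oct4 morpholino effect against uninjected embryos, each time in its own experiment, differed for 876 genes, 555 higher at 44 h and 321 lower. Of 100 splits of the arrays within each time, 3 gave as many, the real one included (highest other split 894). The share was under 0.05, but another split gave more genes. The comparison was also chosen after the data were seen, so chance is not excluded. Without 20 h uninjected replicates 1 and 3 the real count was 529 and 552. Without 20 h Oct4 morpholino replicate 3 it was 573. The Sall4 morpholino effect differed for 227 genes, 100 higher and 127 lower. Of 100 drawn splits, 4 gave as many, the real one included (highest other 388). This share was just under 0.05, but here too another split gave more genes, so chance is not excluded. Without 20 h Sall4 morpholino replicate 3 the real count was 150 genes, and without 44 h uninjected replicate 3 it was 138. Without 44 h Sall4 morpholino replicates 2 and 3 it was 79 and 341. Median centring split it into 134 higher and 105 lower, quantile normalization into 139 and 98, and a trimmed mean into 228 and 139. The latter 2 moved the median of all genes by 0.107 and 0.115 on the log2 scale. The Nanog morpholino effect differed for 128 genes, 95 higher and 33 lower, and 7 of 100 splits gave as many (highest other 202), so chance is not excluded. It was 71 and 79 genes without 20 h control replicates 1 and 3, 82 without 20 h Nanog morpholino replicate 1 and 75 without 44 h Nanog morpholino replicate 1. Exchanging the labels at 44 h alone, which adds the effects of both times, was not among the drawn splits and gave 1542, 578 and 408 genes for Oct4, Sall4 and Nanog, a structure left by the effects themselves.

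Pou5f1 was among the genes that differed over time. Its difference, limma with Benjamini-Hochberg adjustment, was -1.14 on the log2 scale with the Oct4 morpholino (adjusted p = 0.00833, lost under quantile normalization at 0.0662 and with the arrays of the experiment alone at 0.0661). With the Sall4 morpholino it was -1.01 (adjusted p = 0.046). That call was lost under median centring (0.0677), quantile normalization (0.237), a trimmed mean (0.0558) and the arrays of the experiment alone (0.239). It was also lost without any 1 of the 12 arrays (adjusted p of 0.0563 to 0.17) except replicates 1 and 3 of the 44 h Sall4 morpholino (0.0277 and 0.0155).

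Single genes with the largest differences of the Nanog effect between times were Rhov (log2 6.40), Slc25a35 (4.89), Zfp78 (4.60), Erv3 (4.50) and Tent5a (4.45) upwards, and Ptpn22 (-4.88), P2ry14 (-4.40), Runx3 (-4.32), Suclg2 (-4.25) and Cnmd (-4.19) downwards. Their sizes and order hold for the pseudocount of 16 alone: with 1 and 64, Slc25a35 stood at 6.67 and 3.33 and Runx3 at -6.65 and -2.59. Slc25a35 (adjusted p = 0.0393) lost its call without 20 h control replicates 1 (0.119) or 2 (0.102), 20 h Nanog morpholino replicates 1 (0.133) or 2 (0.055), 44 h control replicates 1 (0.0635) or 2 (0.104), or 44 h Nanog morpholino replicates 1 (0.134) or 3 (0.0817). Cnmd (adjusted p = 0.0344) lost it without 20 h control replicates 1 (0.0513), 2 (0.0798) or 3 (0.0668), 20 h Nanog morpholino replicates 2 (0.103) or 3 (0.0716), 44 h control replicates 1 (0.0587) or 3 (0.0726), or 44 h Nanog morpholino replicates 1 (0.119) or 2 (0.0611). Other settings ended calls too: quantile normalization those of Slc25a35 (0.09), Zfp78 (0.0555), P2ry14 (0.0793) and Cnmd (0.0747), a trimmed mean those of Slc25a35 (0.0972), P2ry14 (0.064), Runx3 (0.0589) and Cnmd (0.103). A pseudocount of 1 ended those of Slc25a35 (0.113), Tent5a (0.107) and Cnmd (0.181), and the mean of all probe sets that of Zfp78 (0.0709). With the arrays of the experiment alone none of the 10 passed (adjusted p from 0.0503 for P2ry14 to 0.297 for Slc25a35).

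Outside the named genes, 6767 probe sets without a single gene symbol passed the filter, and some held a signal. With the Oct4, Sall4 and Nanog morpholinos at 44 h, 353, 89 and 295 of them passed the test. Control-injected against uninjected embryos gave 8 in the Oct4 and Sall4 experiment and 68 in the Nanog experiment.

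Knockdown effects at 44 h leaned back towards the 20 h profile: against the 20 h to 44 h change of uninjected embryos in experiments that share no array (for Nanog, across separately labelled experiments), their slopes across genes were -0.200 (Oct4), -0.177 (Sall4) and -0.195 (Nanog). A compressed signal range on the knockdown arrays is argued against by slopes of -0.172, -0.162 and -0.184 with each gene's level in the model. The knockdown effects are against control-injected embryos, so an effect common to every injection is already removed and does not enter these slopes. Control-injected against uninjected embryos had slopes of -0.0378 (Oct4 and Sall4) and -0.0151 (Nanog), which do not test injection as such. Of the genes past the test in both comparisons, 84.6% of 684 (Oct4), 94.3% of 265 (Sall4) and 91.4% of 501 (Nanog) moved back, at least 80.95, 90 and 87.5% without any 1 array, so part of each change may be delayed development, a hypothesis found and tested on the same data. For delay as the whole change, a bound of 90% moving back was set after the result was seen, so each reading holds for that bound only. Such delay is argued against for Oct4, where 105 genes moved further along and the share moving back stayed under 90%. It stays open for Nanog (43 further along), whose share of 87.5 to 93.6% without single arrays lay on both sides of that bound. For Sall4 (15 further along) it was not excluded. Genes past the knockdown test alone, 1105 of 1789 (Oct4), 349 of 614 (Sall4) and 274 of 775 (Nanog), leave this open, since missing a threshold does not show that a gene stayed level over time.

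Gtf2f2 and Rpl39l were lower in control-injected than in uninjected embryos in both 44 h experiments, by a median of -1.74 on the log2 scale. Injection of a morpholino as such is argued against for Gtf2f2 by the knockdown embryos. Against uninjected ones Gtf2f2 stood at 0.71 (Oct4), 0.62 (Sall4) and 0.09 (Nanog). Rpl39l stood at -0.50, -0.68 and -0.28 without passing, in the direction of the control's fall. Injection as a part of the Rpl39l fall therefore stays open. The median of both genes, -0.0944 (-0.155 to -0.0548 without each array in turn), pools these opposite directions. Handling of the arrays stays open, since the genes were picked for being lower in both experiments and their number (2) decides nothing about it. At 20 h, a comparison not used to pick them, both were lower again by at least 3.86 standard errors, Gtf2f2 at -0.85 and Rpl39l at -1.47, although neither passed limma's test (adjusted p = 0.16 and 0.123). A candidate explanation for part of their rise with all 3 knockdown morpholinos is an effect of the control morpholino itself, a hypothesis with no test of its sequence against the genome.

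The stress response list of 24 genes was higher at 44 h by a median of 0.96 with the Oct4 and 0.50 with the Nanog morpholino (adjusted p = 0.00948 and 0.068 with an estimated correlation, so that the Nanog call was lost). Both rises are against control-injected embryos, so an effect common to every injection is already removed and does not enter them. In control-injected against uninjected embryos the list's medians were 0.0278 and -0.0596 (-0.0145 to 0.0998 and -0.0847 to 0.0640 without each array in turn). These medians do not test injection as such. Delay as the whole change is argued against for Oct4, whose list stood 0.477 above 20 h uninjected embryos of a separately labelled experiment (0.277 to 0.518) and whose rise exceeded the fall over time in uninjected embryos of the Nanog experiment by a median of 0.538 (0.380 to 0.671), and is open for Nanog, where 0.117 (-0.0234 to 0.130) crossed 0. Injection of any knockdown morpholino as the whole Oct4 rise is argued against by a list 0.459 above that of Sall4 morpholino embryos (0.409 to 0.622; adjusted p = 0.0142 with an estimated correlation), but as a part of it cannot be told apart, since the Sall4 list stood 0.179 above control-injected embryos (0.0386 to 0.385) without passing (adjusted p = 0.203). A response to the loss of Oct4 may add to the Oct4 rise, as a hypothesis, and an action of that oligomer on other mRNAs was not tested.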

How the results depend on the processing

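Scaling to a trimmed mean, the filter on the arrays' own medians and every alternative of the knockdown against uninjected comparisons across time were chosen only after the result was seen. The count of genes that changed over time in uninjected embryos (3958) and that of the Oct4 morpholino against uninjected embryos across time (876) stayed within 1.5 times under every alternative outside the left-out arrays. For other counts with a value named below the cause was not tested, unless stated.

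Only the arrays of the experiment gave 13 genes with the Oct4 morpholino at 20 h (312 with all arrays), 1043 at 44 h (1789), 117 with Sall4 at 44 h (614), 91 with Nanog at 44 h (775), 481 for Oct4 against Sall4 (1095), and 12 each for the Nanog (128) and Sall4 (227) effects across time. Control-injected against uninjected embryos at 44 h gave 1 gene in the Oct4 and Sall4 experiment (15). Limma gave 0 genes for Sall4 at 20 h (36; 954 at an unadjusted p under 0.05), Nanog at 20 h (96; 1096), and control injection in the Nanog experiment at 20 h (14; 688) and 44 h (54; 1566). This alternative has fewer arrays by construction.

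Uninjected embryos as control gave 1076 (Sall4) and 1296 (Nanog) genes at 44 h and 70 for Nanog at 20 h. Both controls averaged gave 2770 (Oct4), 1323 and 1458, with more arrays by construction. Against uninjected embryos Rpl39l turned to -0.50 (Oct4), -0.68 (Sall4) and -0.28 (Nanog), since it was lower in control-injected ones.

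Quantile normalization gave 195 genes for Oct4 at 20 h and 2 and 12 for control injection in the Nanog experiment at 20 h and 44 h. Median centring gave 55 for Sall4 at 20 h. A trimmed mean gave 100 for Sall4 and 43 for Nanog at 20 h, 13 for control injection at 44 h in the Nanog experiment, 35 for Nanog and 367 for Sall4 across time, and, in limma, 0 for control injection at 20 h (552 at an unadjusted p under 0.05). Uninjected embryos at 20 h differed between experiments in 4994, 3943 and 5330 genes under centring, quantile normalization and a trimmed mean (13790 as deposited), of which each aligns the arrays by another measure. Mamstr in the 20 h control injection turned to -0.00863 under quantile normalization and -0.00614 with a trimmed mean.

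Pseudocounts of 1 and 64 gave 56 and 11 genes for Sall4 at 20 h, 35 and 170 for Nanog at 20 h, 442 and 1266 for Nanog at 44 h, 39 and 303 for Nanog across time, and 10 and 314 for control injection in the Nanog experiment at 44 h. At 20 h that injection gave 52 with 64 and 0 in limma with 1 (546 at an unadjusted p under 0.05). A filter at the 75th percentile gave 9 and 25 genes for it at 20 h and 44 h, and one on the arrays' own medians 29 at 44 h, with other numbers of genes tested.

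The mean of all probe sets gave 194 genes for Oct4 and 16 for Sall4 at 20 h and 3 for control injection in the Oct4 and Sall4 experiment. It turned Srsf6 in Oct4 against Sall4 from -0.85 to 1.37, because its other probe sets stood at 1.01, 2.48 and 2.83. Array weights gave 942 for Oct4 and 15 for Sall4 at 20 h, 700 for Oct4 against Sall4, and for control injection 9 and 192 in the Nanog experiment at 20 h and 44 h and 27 in the other. A variance trend gave 67 for Sall4 at 20 h.

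Replicate numbers of 14 pairs of groups correlated at -0.045 to 0.137. Every value was over 0.1 for control injection at 20 h in the Nanog experiment alone, a hint of pairing that no label states. Every array correlated best with its own number in 3 of the 14, a hint from the data, not the design. Besides that one, these were control-injected against uninjected and against Nanog morpholino embryos of the Nanog experiment at 44 h. With the replicate number as a block, control injection at 20 h in the Nanog experiment gave 8 genes and that in the Oct4 and Sall4 experiment 8. No other count moved by over 1.5 times. The block ended 51 of 483 calls of named genes and 1 list call, translation factors in Oct4 against Sall4 (adjusted p = 0.0652), and changed no other call.

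Leaving out each array in turn gave 97 to 528 genes (Oct4), 30 to 184 (Sall4), 42 to 98 (Nanog) and 7 to 53 (control injection) at 20 h. At 44 h it gave 1161 to 1583 (Oct4), 247 to 801 (Sall4), 400 to 955 (Nanog), 848 to 981 (Oct4 against Sall4), and 4 to 15 and 15 to 114 for control injection in the Oct4 and Sall4 and the Nanog experiment. Across time it gave 71 to 192 (Nanog), 529 to 858 (Oct4), 79 to 341 (Sall4) and 3179 to 3722 (uninjected), and between experiments 13190 to 13690.

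Of the 54 list calls, 3 held with an estimated correlation and 42 with fry, which does not compare a list with other genes. Quantile normalization ended 13, a filter at the 75th percentile 8, a trimmed mean 8, the mean of all probe sets 6, a pseudocount of 1 5, a filter on own medians 2, and a pseudocount of 64 or no filter 1 each. The correlation of Oct4 and Sall4 effects at 44 h (0.53) was 0.40 with uninjected embryos as control of Sall4, which removes the shared arrays, and 0.47 to 0.58 without each array in turn. Over all alternatives, values of named genes kept their direction and side of the threshold in 8838 cases, lost the call in 1401 and gained it in 2, both under quantile normalization: Pou5f1 in the Nanog effect across time (-1.25, adjusted p = 0.0126) and Sall4 over time in uninjected embryos (0.51, adjusted p = 0.0208). In the settings run for lists, list calls kept both in 647 cases and were lost in 108. Other correlations moved by less than the spread between left-out arrays in 51 cases and by more in 12. A gene that a filter removed has no value under it. Near the floor, where signal over background is low and 2.43% of values are exactly 1, the pseudocount sets the size of a change.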

Other observations

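The overlaps and correlations of effects across time and the splits by replicate pairs were chosen only after the result was seen, while the other splits of the arrays given here were planned.

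With the Oct4 morpholino, calls at both times overlapped, against uninjected embryos at 20 h and control-injected ones at 44 h. Of the 285 genes lower at 20 h and the 957 lower at 44 h, 65 were in both lists (17.6 for independent lists), and 8 were higher at both (1.45). Calls of both times rest on 1 estimate of each gene's spread, with each morpholino, so independent lists are too low a baseline. Of translation factors, Eif3e stood at -2.09 at 20 h and -2.74 at 44 h on the log2 scale, Eif2s3x at -0.74 and -2.82, and Eif4e at -0.55 and -1.61. Mcm5, of the replicative helicase, stood at -1.55 and -2.23, Hat1, a histone acetyltransferase, at -1.29 and -2.03, Sirt1, a deacetylase, at -1.72 and -1.57, and Cct5, a chaperonin subunit, at -0.89 and -1.57. Kank4 (-3.49 and -1.65), Acyp1 (-3.28 and -2.94), Cse1l, a nuclear export receptor (-1.59 and -2.07), and Sall4 (-0.76 and -0.99) were lower at both times as well. Among genes higher at both times were Gadd45g (1.70 and 2.91), Id1, an inhibitor of helix-loop-helix factors (1.24 and 1.89), Rps6 (2.40 and 2.06) and Sfi1 (2.27 and 1.58). Sirt1, Cct5, Cse1l and Id1 lie outside the rule for named genes and were chosen after their values were seen. Calls in opposite directions were fewer: 1 gene higher then lower (1.67 for independent lists), Hadh, a mitochondrial dehydrogenase (2.53 and -2.39), and 6 lower then higher (15.3). Of the 65 lower genes, 6 were also lower with the Sall4 morpholino at 44 h.

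The other morpholinos shared fewer calls across time. Sall4, with the same kinds of control as Oct4, had 1 gene higher (0.422 for independent lists) and 1 lower (0.277) at both times. Nanog, against control-injected embryos at both, had 4 higher (1.24), 7 lower (0.938) and 2 higher then lower (0.563). The 4 include Rpl39l, which was lower in control-injected embryos and stood at 0.11 (20 h) and -0.28 (44 h) against uninjected ones. Across genes, which are not independent replicates, effects at both times correlated with r = 0.145 (Oct4), 0.0521 (Sall4) and 0.139 (Nanog).

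The 6 arrays of a comparison make 10 splits, the real one included, too few for a share under 0.05. At 20 h, the real split gave 312 genes for Oct4 (highest other 42), 96 for Nanog (27), 36 for Sall4 (47, so that 2 splits gave as many) and 14 for control injection in the Nanog experiment (23, so that 4 did). At 44 h it gave 1789 for Oct4 (18), 614 for Sall4 (9), 775 for Nanog (57), 1095 for Oct4 against Sall4 (102), 15 for control injection in the Oct4 and Sall4 experiment (3) and 54 in the Nanog experiment (37). If the replicate numbers pair the arrays of control injection at 20 h, which no label states, 4 splits part all 3 pairs. Of these, the real one gave 14 genes and the others 7, 6 and 1. With the replicate number as a block the real one gave 8 and the others 7, 8 and 0. Uninjected embryos over time gave 3958 (26). In each comparison besides Sall4 and control injection at 20 h, the real split was the 1 split with so many genes. For uninjected embryos between experiments at 20 h, 1 of 100 splits reached the 13790 genes of the real one (highest other 13718). That count is set by the difference in scale, so the share bears on the scale and says nothing of genes beyond it. Such splits place the 3 arrays of the higher scale unequally, a structure of the samples.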
